A study of Mus musculus with 7 samples.

How the data were processed

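RNA was sequenced from 3 control mammary glands and 4 mammary tumours of ECD transgenic mice. Per the labels' protocols, total RNA was taken with Trizol from glands or from the centre of each tumour, treated with DNase I and cleaned on columns. Libraries were made with a TruSeq v2 kit, which does not mark the strand, and read as pairs of 75 bases on a HiSeq instrument. The submitters' processing notes name STAR 2.5, RSEM 1.3, limma and the mouse build GRCm38, without saying which did what. The annotation release, filters and strand setting are not given in the sources used here.

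The deposited tables hold 1 estimated count per gene for each of 50600 genes, 1 table per library. Their value column is headed TPM. Its sums differ between libraries, from 5148438 to 35631279, whereas TPM sums to 1000000 in every library. Between 2.34% and 6.14% of values were not whole. The values were therefore read as the authors' expected counts and rounded to whole numbers. No row lacked a gene. Gene symbols and identifiers were those of the tables. Positions came from GENCODE release M21 on GRCm38, which held 50376 of the 50600 identifiers. Because strand was not marked, reads of overlapping genes on opposite strands cannot be told apart. Counts of near-identical copies, such as histone, Dcpp, Krt6 and U1 RNA genes, are uncertain.

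Groups were taken from the sample labels. The 4 tumours are adenosquamous tumours 1a and 1b, spindle cell tumour 3 and papillary tumour 4. The series' design text calls the glands and tumours independent, but tumours 1a and 1b share a number and the labels do not say whether they came from 1 animal. No pairing, batch or date is given. No library pair within a group had identical values. The chi-square per degree of freedom between libraries of a group was 85.0 to 374.9 (107.9 between tumours 1a and 1b), so none was a repeat reading of another. The values do not tell whether tumours 1a and 1b came from 1 animal. Each library was counted as 1 replicate, which for that pair is an assumption.

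Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test after TMM scaling (factors 0.551 to 1.605). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14149 genes for the 7 libraries and 14708 for the comparison of the 2 adenosquamous tumours with the 3 glands. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 counted as passing. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM, counts scaled to a library total of 1000000, used the TMM-scaled library sizes, and log2 CPM used a prior count of 2. Means of CPM are given with SD. The 31 gene lists, chosen beforehand, hold 579 memberships, of which 578 were matched. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts of members that passed are given over all genes and also adjusted over the list alone.

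Genes to name were set by a rule written beforehand. The rule took 20 fixed genes. It added the 8 highest and 8 lowest log2 fold changes among genes that passed, with an average log2 CPM of at least 3 and all tumours on 1 side of all glands. Gene models without a proper symbol, antigen receptor segments and pseudogenes were left out. For each list it took the 2 members with the smallest adjusted p in the main direction and the member that changed most the other way. If no member passed, it took the member with the smallest p. For the adenosquamous comparison it took the fixed genes and the 4 highest and 4 lowest. For tumour types it took the 6 genes with the largest log2 CPM gap to all libraries of other types, at 10 CPM or more. Other named genes were chosen after their values were seen, and the text says so.

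On simulated counts with 200 changed genes, the tumour comparison recovered 8% of genes changed by 2 on the log2 scale and 58% of those changed by 4, and called 2 of 13929 unchanged genes. The adenosquamous comparison recovered 11% and 72%, and called 14 of 14488. Unchanged genes thus made up 2 of 68 calls in the tumour comparison and 14 of 99 in the adenosquamous one. In the adenosquamous simulation false calls therefore exceeded the 0.05 aimed at. In the data 4093 and 4399 genes were at unadjusted p under 0.05 in these comparisons. With more changed genes the Benjamini-Hochberg threshold is less strict, so these shares do not give the recovery in the data. The common biological coefficient of variation was 0.6 over the 7 libraries and 0.504 over the 5. Exact 95% intervals of the per-library shares given here reach at most 0.0432 percentage points to each side and cover counting error only. Where a group held no count, a fold was computed against a floor of 3 counts over the group, or none is given.

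Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, median-ratio and upper-quartile scaling, no filter, a filter of 10 CPM in 2 libraries, a robust fit, stricter thresholds, and leaving out each library. Tumours 1a and 1b were also added into 1 library, and tumour types weighted equally. Chosen after seeing the data were protein-coding genes outside mitochondrial DNA only, control gland 2 as the only control, and leaving out control gland 1 together with the spindle cell tumour or with adenosquamous tumour 1b. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.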

Results

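Transcripts were counted in mammary tumours of ECD transgenic mice and in control mammary glands. Ecd (ecdysoneless) encodes a cell cycle regulator that binds the R2TP chaperone complex and the spliceosome factor Prpf8. The species of the transgene is not given in the sources used here, and the tables count the mouse gene. The libraries came from 3 control glands, adenosquamous carcinomas 1a and 1b, spindle cell carcinoma 3 and papillary carcinoma 4.

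Total counts were 5148438, 35631279 and 34079708 in control glands 1, 2 and 3. They were 7986916 and 5420562 in adenosquamous tumours 1a and 1b, 6654544 in the spindle cell tumour and 28638143 in the papillary tumour. Genes of mitochondrial DNA took 64.83%, 48.36% and 54.89% of counts in the glands and 18.34%, 23.78%, 19.89% and 32.61% in tumours 1a, 1b, 3 and 4. On the first principal component, with 46.7% of the variance, glands lay between -147.51 and -62.41 and tumours between 51.63 and 100.38.

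Which genes differ between tumours and normal glands is the question the series' title and design text set. Proliferation genes were higher in the tumours, and genes of fat cells and fatty acid metabolism were lower. RNA came from glands or tumour centres, so a lower share of fat cells in tumours cannot be told apart from lower expression within cells. Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361, GRCm38), was at 15.4 ± 11.2 CPM in glands (SD, n = 3) and 320.1 ± 74.5 CPM in tumours (SD, n = 4), a 20.6-fold rise (log2 4.37, SE 0.57, adjusted p = 0.0101). Adipoq, which encodes the fat cell hormone adiponectin, fell from 351.4 ± 33.8 CPM to 1.86 ± 3.58 CPM (log2 -7.55, SE 1.80, adjusted p = 0.0449), with 7.24 CPM in tumour 1a and at most 0.136 in the others (log2 -12.22 without 1a). Without control gland 2 the log2 fold change of Mki67 was 5.16, but Mki67 did not pass without control gland 3. The call of Adipoq was lost without any 1 gland, without tumour 1b or without the spindle cell tumour. In all, 1199 of 14149 genes passed, 552 higher and 647 lower in tumours. This count depended on single libraries: it was 403, 566 and 97 without control gland 1, 2 or 3, 416 without adenosquamous tumour 1b and 596 without the spindle cell tumour. No gene passed in edgeR with control gland 2 as the only control (1655 at unadjusted p under 0.05) or without control gland 1 and the spindle cell tumour (3441), both chosen after seeing the data.

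Mouse Ecd (ENSMUSG00000021810, chromosome 14, 20319852 to 20348121, GRCm38) was at 15.5 ± 3.23 CPM in glands (n = 3) and 19.2 ± 2.43 CPM in tumours (n = 4), a difference that did not pass (log2 0.30, SE 0.26, adjusted p = 0.463). This value does not check the transgene, whose transcript is not counted separately. Of 12 measured genes of the ECD partner list, which includes Ecd itself, 1 rose, 0 fell and 11 did not pass (3 rose adjusted over the list alone). Eftud2, a U5 spliceosome GTPase, rose 2.91-fold (SE 0.25 on the log2 scale, adjusted p = 0.0156). The list did not pass (camera adjusted p = 0.0805), but did without control gland 3 (0.0387) or tumour 1b (0.0358). Without control gland 1, 2 or 3, 0 of its genes passed in edgeR (4, 3 and 3 at unadjusted p under 0.05), and 2 passed without the papillary tumour. Of 15 genes of m6A RNA methylation, 0 passed in edgeR, also adjusted over the list alone (2 at unadjusted p under 0.05, while 1 passed in DESeq2 and 1 in limma-voom), and the list did not pass (adjusted p = 0.608). Mettl3, the catalytic subunit of the m6A writer, had a log2 difference of 0.06 (SE 0.26, adjusted p = 0.904), and Rbm15b was at 15.8 ± 5.46 CPM in glands and 39.2 ± 8.12 CPM in tumours (adjusted p = 0.0522).

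Mitosis genes and most DNA replication genes rose. All 24 measured mitosis genes rose (24 adjusted over the list alone), with a median log2 fold change of 4.25 (camera adjusted p = 1.1e-42 and adjusted p = 0.141 with an estimated correlation). Prc1, a protein of the central spindle, rose 19.7-fold (SE 0.43 on the log2 scale, adjusted p = 0.00805), and Cenpf, a kinetochore protein, 17.9-fold (SE 0.43, adjusted p = 0.00805). Of 23 DNA replication and G1/S genes, 18 rose, 0 fell and 5 did not pass (21 rose adjusted over the list alone), with a median of 2.42 (adjusted p = 1.5e-17 and adjusted p = 0.176 with an estimated correlation). The helicase subunit gene Mcm5 rose 11.6-fold (adjusted p = 0.0103), and Rrm1, of ribonucleotide reductase, 3.42-fold (adjusted p = 0.0109). Myc, a growth-driving transcription factor, had a log2 difference of 1.53 (SE 0.98, adjusted p = 0.336). Its log2 CPM was 0.49 in the spindle cell tumour and 5.07 to 5.65 in the other tumours, against 2.34 to 4.02 in glands. Of 27 nucleolar and ribosome assembly genes known to respond to Myc, 6 rose, 0 fell and 21 did not pass (15 rose adjusted over the list alone), with a median of 0.94 (adjusted p = 3.6e-05 and adjusted p = 0.449 with an estimated correlation). Nop56 rose 2.99-fold (adjusted p = 0.0143) and Mybbp1a 2.11-fold (adjusted p = 0.0274). Without control gland 3, 6 mitosis, 0 replication and 0 nucleolar genes passed in edgeR (20 and 17 of the latter pair at unadjusted p under 0.05). Replication genes that passed were 7, 8, 9, 7 and 9 without control gland 1, control gland 2, tumour 1a, tumour 1b or the spindle cell tumour, and nucleolar genes 0, 0, 2, 1 and 1 (16 and 12 at unadjusted p under 0.05 for the glands).

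Most measured transcripts of fat cells, fatty acid synthesis and fatty acid oxidation fell. The adipocyte list mean was 8.0 log2 CPM in glands and 1.47 in tumours. Whether the falls in fatty acid genes follow fat cell content was not tested. Of 22 adipocyte genes, 0 rose, 15 fell and 7 did not pass (18 fell adjusted over the list alone), with a median of -6.04 (adjusted p = 8.7e-21 and adjusted p = 0.143 with an estimated correlation). Lep, the gene of leptin, fell from 106.6 ± 52.0 CPM (n = 3) to 0.0933 ± 0.0702 CPM (n = 4; log2 -9.93, SE 0.63, adjusted p = 0.00612). Lipe, which encodes hormone-sensitive lipase, fell 15.6-fold (adjusted p = 0.0101). Of 17 lipogenesis genes, 10 fell, 0 rose and 7 did not pass (11 fell adjusted over the list alone), with a median of -3.52 (adjusted p = 5.6e-11 and adjusted p = 0.358 with an estimated correlation). The fatty acid elongase Elovl6 fell 31.9-fold (adjusted p = 0.00887) and Insig1, a sterol sensor partner, 11.5-fold (adjusted p = 0.00675). Of 18 fatty acid oxidation genes, 11 fell, 0 rose and 7 did not pass (14 fell and 1 rose adjusted over the list alone), with a median of -2.10 (adjusted p = 6.0e-12 and adjusted p = 0.143 with an estimated correlation). Decr1 and Hadhb, enzymes of mitochondrial beta-oxidation, fell 8.94-fold and 6.97-fold (adjusted p = 0.00887 for both). Adipocyte, lipogenesis and fatty acid oxidation genes that passed were 7, 5 and 5 without control gland 1, 8, 6 and 7 without gland 2, 1, 2 and 3 without gland 3, and 4, 6 and 5 without tumour 1b. They were 16, 6 and 9 without tumour 1a and 8, 6 and 6 without the spindle cell tumour.

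Energy metabolism genes did not move as 1 group. Of 22 nuclear genes of oxidative phosphorylation, 6 fell, 0 rose and 16 did not pass (18 fell adjusted over the list alone), with a median of -1.11 (adjusted p = 2.4e-10 and adjusted p = 0.443 with an estimated correlation). Sdha, of succinate dehydrogenase, fell 4.16-fold (adjusted p = 0.00905) and Ndufs1, of complex I, 3.85-fold (adjusted p = 0.0101). The mitochondrial share of counts was also lower in every tumour than in every gland. Most of that share was the ribosomal RNA mt-Rnr2. It took 49.07%, 33.24% and 42.03% of counts in glands 1, 2 and 3 and 14.6% to 24.17% in tumours. The rest of the mitochondrial share was also lower in every tumour than in every gland. That rest was not split by gene, so it says little about single mitochondrial genes. Of 21 glycolysis genes, 1 rose, 3 fell and 17 did not pass (2 rose and 4 fell adjusted over the list alone), and the list did not pass (median -0.07, adjusted p = 0.564). Slc2a1, the glucose transporter GLUT1, rose 7.76-fold from 6.83 ± 1.86 CPM (n = 3) to 53.8 ± 25.6 CPM (n = 4; adjusted p = 0.0136). Hk2, a hexokinase, fell 3.97-fold (adjusted p = 0.0282), Pfkfb3, which makes an activator of glycolysis, 4.90-fold (adjusted p = 0.0144), and Aldoa by 2.20 on the log2 scale. Aldoa was named after its values were seen. Ldha (log2 -0.64, SE 0.37, adjusted p = 0.279) and Pkm (log2 0.17, SE 0.43, adjusted p = 0.825) did not pass. Over both lists 10 genes passed, but 4 without control gland 1, 1 without control gland 3 and 17 without the papillary tumour.

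Skeletal muscle transcripts separated the glands from each other. The mean log2 CPM of 17 muscle genes was 9.66 and 10.93 in control glands 1 and 3 but 1.15 in control gland 2, against 4.27, 1.72, -1.31 and -1.68 in tumours 1a, 1b, 3 and 4. No muscle gene passed in edgeR over all genes (17 at unadjusted p under 0.05, while 16 passed in DESeq2 and 0 in limma-voom), 17 fell adjusted over the list alone, and the median was -7.47 (camera adjusted p = 1.5e-06 and adjusted p = 0.557 with an estimated correlation). Without control gland 2, 4 of them passed, and against that gland alone the median was 1.22. Casq1, a muscle calcium store protein, had a log2 difference of -7.64 (SE 1.92, adjusted p = 0.0517). With control gland 2 as the only control, the medians of oxidative phosphorylation, fatty acid oxidation and adipocyte genes were -0.99, -2.08 and -5.67.

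Epithelial genes differed in part. Krt14, a basal keratin, rose from 5.84 ± 3.62 CPM (n = 3) to 358.6 ± 373.1 CPM (n = 4; log2 5.91, SE 1.36, adjusted p = 0.0407, but 5.03 and 0.0567 without tumour 1a and 6.50 and 0.125 without control gland 3), and Krt8, a luminal keratin, from 44.4 ± 13.9 CPM to 207.2 ± 95.2 CPM (log2 2.22, SE 0.48, adjusted p = 0.0343). Krt5 (log2 4.61, adjusted p = 0.135), Krt18 (1.88, adjusted p = 0.134), Trp63 (1.01, adjusted p = 0.611), Cdh1 (1.56, adjusted p = 0.1001), Vim (0.56, adjusted p = 0.688), Esr1 (-2.54, adjusted p = 0.139) and Pgr (-4.19, adjusted p = 0.0653) did not pass. Of 16 basal and myoepithelial genes, 3 rose, 0 fell and 13 did not pass (3 rose and 1 fell adjusted over the list alone). They were Krt14, Itgb4 (8.61-fold, adjusted p = 0.0345) and Lamb3 (9.41-fold, adjusted p = 0.0368), and the list did not pass (adjusted p = 0.293). Of 25 luminal genes only Krt8 rose in edgeR, 0 fell and 24 did not pass (1 rose adjusted over the list alone; list adjusted p = 0.396). In DESeq2 7 luminal genes rose and 4 fell, and in limma-voom 1 rose and 3 fell. Of 9 measured squamous genes, 1 rose and 8 did not pass (3 rose adjusted over the list alone), with a median of 4.26 (adjusted p = 0.0107 and adjusted p = 0.508 with an estimated correlation). The papillary tumour's list mean, 0.05 log2 CPM, lay within the glands' range of -0.90 to 0.43. Sfn, an epithelial 14-3-3 protein, rose 37.2-fold (adjusted p = 0.0276). None of 15 milk protein and lactation genes passed in edgeR, also adjusted over the list alone (0 at unadjusted p under 0.05, while 0 passed in DESeq2 and in limma-voom). Their median was 1.36 and mean 1.57, while camera's direction was down (adjusted p = 0.655). Wap, a milk whey protein, had a log2 difference of 5.50 (SE 2.86, adjusted p = 0.243). Over these lists 5 genes passed, but in edgeR 0 without control gland 1, 2 or 3 or tumour 1b (20, 13, 16 and 22 at unadjusted p under 0.05) and 15 without the papillary tumour. The squamous list did not pass without tumour 1a (adjusted p = 0.113) or 1b (0.102), while the luminal list passed without 1a (0.0267) and without the papillary tumour the basal list passed as higher (0.00367) and the milk list as lower (0.00432, with its median turned to -2.68).

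Among stress and signalling lists, the unfolded protein response and interferon response lists passed in camera, though not in fry (fry adjusted p = 0.0571 for both). Of 23 unfolded protein response genes, 4 rose, 0 fell and 19 did not pass (10 rose adjusted over the list alone), with a median of 0.61 (adjusted p = 0.0112 and adjusted p = 0.614 with an estimated correlation). They were Hyou1 (2.46-fold, adjusted p = 0.0322), Eif2ak3 (2.05-fold, adjusted p = 0.0347), Sdf2l1 (log2 2.01) and Pdia4 (log2 1.39), the last pair named after seeing their values. Hspa5, the chaperone BiP, had a log2 difference of 0.98 (SE 0.28, adjusted p = 0.0718). Of 17 interferon response genes, 3 rose, 0 fell and 14 did not pass (7 rose adjusted over the list alone; median 1.86, adjusted p = 0.00273 and adjusted p = 0.493 with an estimated correlation). They were Oasl2 (5.28-fold, adjusted p = 0.0182), Isg15 (9.45-fold, adjusted p = 0.0208) and Irf7 (log2 2.98), the last named after seeing its value. Of 16 hypoxia genes Ero1l rose 3.42-fold (adjusted p = 0.0240), Bnip3 fell 3.98-fold (adjusted p = 0.0156) and 14 did not pass (4 rose and 1 fell adjusted over the list alone; list adjusted p = 0.0775). Of 17 p53 target genes, Zmat3 (3.34-fold, adjusted p = 0.0392) and Bax (5.04-fold, adjusted p = 0.0480) rose and 15 did not pass (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.0805). Of 15 Wnt target genes, Ccnd1, the gene of cyclin D1, rose 16.9-fold (log2 4.08, adjusted p = 0.0343), with 642 CPM in the papillary tumour and 79.8 to 174 in the others (log2 2.99 without it, adjusted p = 0.0153), and 14 did not pass (1 rose adjusted over the list alone; list adjusted p = 0.252). None of 16 receptor tyrosine kinase and ligand genes passed in edgeR, also adjusted over the list alone (5 at unadjusted p under 0.05, while 5 passed in DESeq2 and 1 in limma-voom, list adjusted p = 0.752), and Erbb2 had a log2 difference of 1.23 (SE 0.33, adjusted p = 0.0596). Over these lists 12 genes passed, but 2 without control gland 1 or 2, 5 without the spindle cell tumour, and in edgeR 0 without control gland 3 or tumour 1b (34 and 36 at unadjusted p under 0.05). The p53 list passed without control gland 3, the spindle cell or the papillary tumour (adjusted p = 0.0411, 0.0336 and 0.0335), the hypoxia list without control gland 3 or the papillary tumour (0.0252 and 0.00660), and the Wnt list without the papillary tumour (0.00758).

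Matrix genes and markers of other cells in the tissue were uneven. Of 15 matrix protease and inhibitor genes, the collagenase gene Mmp13 rose (log2 10.34, SE 2.45, adjusted p = 0.0444, with 269.6 and 144.8 CPM in tumours 1a and 1b but 1.48 and 5.40 in tumours 3 and 4) and 14 did not pass (7 rose adjusted over the list alone; list adjusted p = 0.0445 and adjusted p = 0.758 with an estimated correlation). The glands held 4 counts of Mmp13 and the tumours 4401 (95% counting interval of the ratio 412 to 3878), and its call was lost without any 1 gland or without 1a or 1b. Its log2 fold change was 9.30 without 1a (adjusted p = 0.0629), 9.69 without control gland 2 (0.139) and 11.49 without control gland 3 (0.1485). The spindle cell tumour's list mean, 2.32 log2 CPM, lay within the glands' range of 1.64 to 2.64. Of 17 mesenchymal genes, Tnc, a matrix glycoprotein, rose 61.4-fold (adjusted p = 0.0349) and 16 did not pass (1 rose adjusted over the list alone; list adjusted p = 0.487). Tnc was at 22.6 CPM in the spindle cell tumour, against 720 to 1401 in the other tumours and 10.3 to 14.65 in glands. Its call was lost without any 1 gland or without 1a or 1b. None of 21 collagen and matrix genes passed in edgeR, also adjusted over the list alone (6 at unadjusted p under 0.05, while 6 passed in DESeq2 and 2 in limma-voom, list adjusted p = 0.409), with Col11a1 at a log2 difference of 3.96 (SE 1.06, adjusted p = 0.0610). The macrophage list was higher (median 2.67, adjusted p = 0.00459 and adjusted p = 0.623 with an estimated correlation), yet its 1 member to pass in edgeR, the scavenger receptor gene Cd163, fell 18.6-fold (adjusted p = 0.0201, 30.1-fold without tumour 1a), and 18 of 19 did not pass (11 rose and 1 fell adjusted over the list alone). In DESeq2 13 macrophage genes rose and 1 fell, and in limma-voom 0 rose and 1 fell. The spindle cell tumour's list mean was 2.90 log2 CPM, within the glands' range of 2.75 to 3.81, against 4.70 to 6.40 in the other tumours. Endothelial genes were lower (median -1.08, adjusted p = 0.00137 and adjusted p = 0.614 with an estimated correlation), and Sox17 fell 9.01-fold (adjusted p = 0.0337) while 15 of 16 did not pass (1 fell adjusted over the list alone). Tumour 1a's list mean of 3.82 lay within the glands' range of 3.27 to 4.50. Nerve and Schwann cell genes were lower (median -1.49, adjusted p = 0.0149 and adjusted p = 0.493 with an estimated correlation). Of 9 measured, 2 fell, 0 rose and 7 did not pass (4 fell adjusted over the list alone). Erythrocyte genes were lower (median -2.54, adjusted p = 0.00451 and adjusted p = 0.493 with an estimated correlation), with Hba-a1 falling 12.1-fold (adjusted p = 0.0478, but 6.72-fold and 0.159 without control gland 3) and 4 of 5 not passing (3 fell adjusted over the list alone), though tumour 1a's list mean of 2.22 was at the level of control gland 1 (2.21). Over these lists 7 genes passed, but 1 without control gland 1, 3 without control gland 2, 12 without tumour 1a, and in edgeR 0 without control gland 3 or tumour 1b (28 and 38 at unadjusted p under 0.05). The protease list did not pass without tumour 1a or 1b (adjusted p = 0.208 and 0.0519), the collagen list passed without the spindle cell or papillary tumour (0.0322 and 0.0488) and the mesenchymal list without the spindle cell tumour (0.0426).

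Lymphocyte and neutrophil lists did not pass, and none of their members did in edgeR, also adjusted over the list alone. At unadjusted p under 0.05 in edgeR there were 0 B cell, 0 T and NK cell and 2 neutrophil genes. In DESeq2 0, 0 and 2 passed, and in limma-voom 0 of each (1, 0 and 0 at unadjusted p under 0.05). The B cell list (3 genes measured, adjusted p = 0.722) was at 4.89 log2 CPM in control gland 2 and 4.8 in adenosquamous tumour 1a, and between -1.05 and 1.02 in the other 5 libraries. Ighm had a log2 difference of -0.89 (SE 1.71, adjusted p = 0.762). The T and NK cell list (7 genes, adjusted p = 0.390) was at 4.35 and 3.32 in the same pair of libraries and between -0.82 and 0.24 elsewhere. Cd3e was at 10.3 ± 12.4 CPM in glands and 2.60 ± 3.58 CPM in tumours (adjusted p = 0.342). The T and NK cell list passed as lower without control gland 3 or tumour 1a (0.0218 and 0.0471). Of 5 neutrophil genes (list adjusted p = 0.267), Csf3r had a log2 difference of 4.02 (SE 1.29, adjusted p = 0.0928). The neutrophil list passed as higher without control gland 1, 2 or 3 (0.0164, 0.0353 and 0.0312) or the spindle cell tumour (0.0336), while 1 B cell gene fell without tumour 1a.

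**Figure D1:**
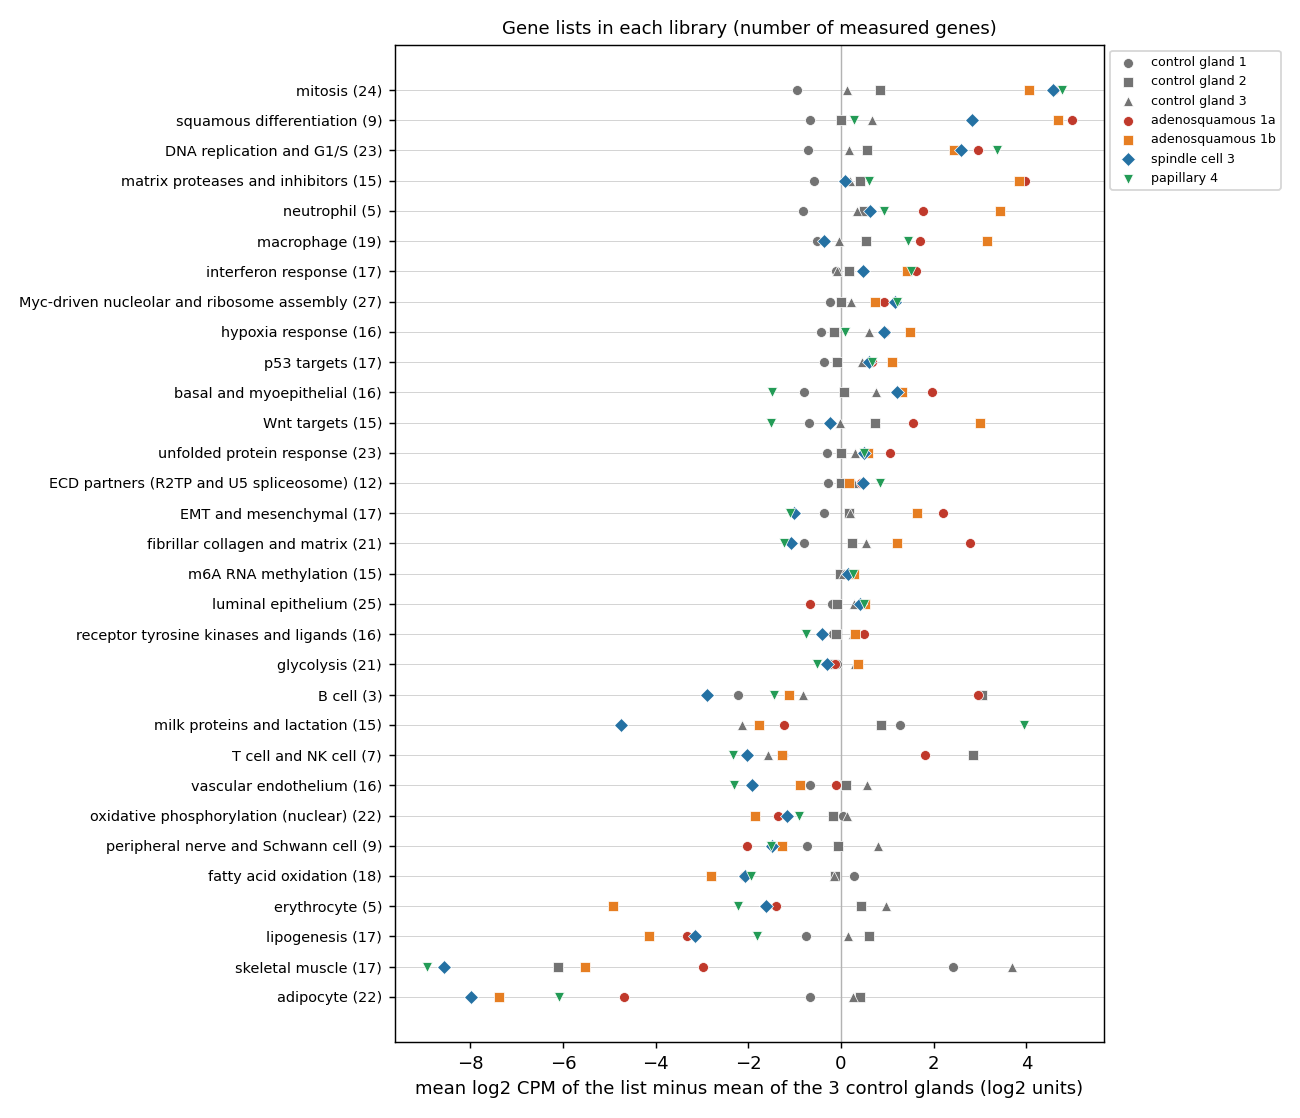
Mean log2 CPM of each gene list in each of the 7 libraries, minus the mean of the 3 control glands, with the number of measured genes after each name; grey points are glands and coloured points are tumours. The 4 tumours lie 4.05 to 4.76 above the gland mean for mitosis genes and at -4.68 to -7.98 for adipocyte genes.

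The largest rises that fit the naming rule were in Mmp13, Tnc, Krt14, Ccnb1, Iqgap3 and transcripts of histone and U1 RNA copies. Ccnb1, the gene of cyclin B1, rose from 0.216 ± 0.187 CPM (n = 3) to 14.7 ± 4.95 CPM (n = 4; log2 5.68, SE 0.61, adjusted p = 0.00806), and Iqgap3, a scaffold protein, 47.4-fold (adjusted p = 0.00982). Rn7s1, Rn7s2 and Rn7sk, RNAs without a poly(A) tail, took 2.23%, 5.35% and 2.59% of counts in glands 1, 2 and 3 and 15.53%, 6.28%, 13.77% and 9.29% in tumours 1a, 1b, 3 and 4. Hist1h2bb (63.3-fold, adjusted p = 0.0151), Hist1h2ai (55.3-fold, adjusted p = 0.0402) and Rnu1b6 (42.1-fold, adjusted p = 0.0377) have near-identical copies, so their counts are uncertain. Whether the higher share of RNA without a poly(A) tail in the tumours also raised these counts was not tested. The largest falls were in Lep, Angptl8, Negr1, Ces1f, Retn, Car3, Fsd2 and Ankef1. The neuronal adhesion gene Negr1 fell from 34.7 ± 5.97 CPM to 0.0600 ± 0.0805 CPM (log2 -8.85, SE 0.67, adjusted p = 0.00612), and the carboxylesterase gene Ces1f 349-fold (adjusted p = 0.00675). Angptl8, which lies within Dock6 on the opposite strand, had 3 counts in the 4 tumours and 2267 in the 3 glands, a pooled ratio of 787 (95% counting interval 269 to 3820; adjusted p = 0.0110). Control gland 2 held 2099 of the gland counts, at 66.2 CPM against 7.07 and 7.02 in glands 1 and 3. The interval covers counting error and not that spread. Retn, the gene of resistin, fell 319-fold (adjusted p = 0.0166), Car3, a carbonic anhydrase, 311-fold (adjusted p = 0.0395), Fsd2 286-fold (adjusted p = 0.0205) and Ankef1 273-fold (adjusted p = 0.00982). Fsd2 was at 63.7 and 109.5 CPM in control glands 1 and 3, which held muscle transcripts, and at 3.15 CPM in control gland 2. Tumour 1a held most of what was left of several: without it the log2 fold changes were -11.30 for Car3, -10.98 for Retn, -9.98 for Ankef1, -9.55 for Fsd2, -9.50 for Negr1 and -9.07 for Ces1f. Without control gland 3, Car3 (log2 -7.58, adjusted p = 0.116) and Fsd2 (-7.30, 0.0761) did not pass, and Iqgap3 was at 6.36. Without control gland 2, Hist1h2ai did not pass (6.86, 0.0878), Hist1h2bb was at 8.38 and Angptl8 at -6.96, and without control gland 1 Rnu1b6 was at 7.57. Of 53 named genes that passed, 13 did so with each of the 7 libraries left out in turn, and 24, 28, 13, 25 and 34 passed without control gland 1, 2 or 3, tumour 1b or the spindle cell tumour.

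**Figure D2:**
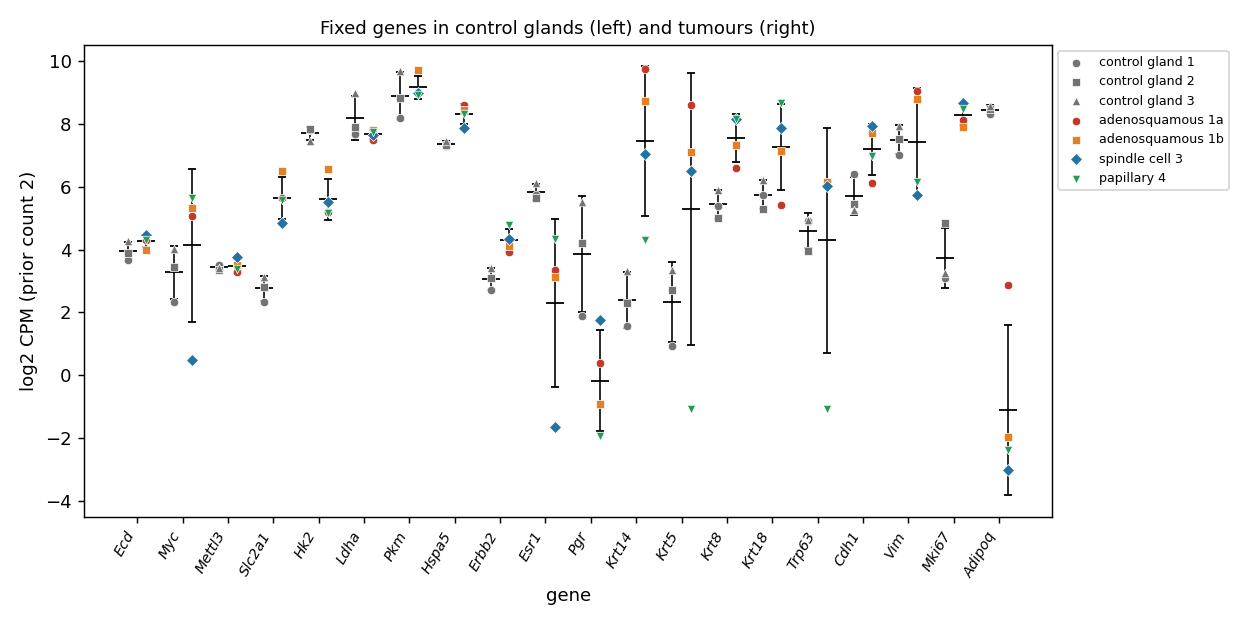
Log2 CPM of the 20 fixed genes in the 3 control glands (left of each pair) and the 4 tumours (right), 1 point per library; bars are the mean and SD of log2 CPM. Mki67 lies higher and Adipoq lower in every tumour than in every gland, while the spindle cell tumour has the lowest Myc value of the 7 libraries, at 0.49.

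The 2 adenosquamous tumours were then compared with the 3 glands, the comparison for the tumour type with more than 1 library. Of 16 squamous and 16 protease genes, 10 each rose, and of 22 fat cell and 22 oxidative phosphorylation genes, 14 each fell. Of 31 lists, 23 passed in camera, 12 in fry and 0 in camera with an estimated correlation (6 at unadjusted p under 0.05). Whether both tumours came from 1 animal is not given. Krt14 rose from 5.84 ± 3.62 CPM (n = 3) to 641.4 ± 302 CPM (n = 2; log2 6.69, SE 0.68, adjusted p = 0.0183), and Krt5 from 6.11 ± 4.18 CPM to 263.8 ± 177.3 CPM (log2 5.32, SE 0.77, adjusted p = 0.0214), with 389.2 CPM in 1a and 138.4 in 1b (log2 4.39 and adjusted p = 0.0691 without 1a, 5.93 and 0.0662 without 1b). Of 14708 genes, 1525 passed, 737 higher and 788 lower. In edgeR 0 passed without control gland 3 (3471 at unadjusted p under 0.05), without tumour 1b (2994), with control gland 2 as the only control (2898), or without control gland 1 and tumour 1b (3839), the last pair chosen after seeing the data. Counts were 690 without control gland 1 and 90 without tumour 1a.

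The genes with the largest rises were epidermal and matrix-degrading. Dsg3, an epidermal desmosome cadherin, had 0 counts in the glands and 1014 in the tumours, at least 985-fold higher (adjusted p = 0.0183). Mmp10, a stromelysin, had 0 and 1000 (922 in tumour 1a and 78 in 1b), at least 971-fold higher (adjusted p = 0.0328, and 0.0855 without 1a), and Krt6b, a keratin of wounded epidermis with a near-identical copy, 0 and 446, at least 433-fold higher (adjusted p = 0.0183). Mmp13 rose from 0.0579 ± 0.0747 CPM (n = 3) to 207.2 ± 88.3 CPM (n = 2; log2 11.27, SE 0.73, adjusted p = 0.0170). The largest falls were again in Lep, Angptl8, Negr1 and Ces1f. The intervals given for them cover counting error and not the spread between glands. Pooled ratios of glands to tumours were 1252 for Lep (2 tumour counts, 95% counting interval 347 to 10340; adjusted p = 0.0180), 778 for Angptl8 (1 count, 140 to 30760; adjusted p = 0.0416), 356 for Negr1 (2 counts, 98.5 to 2945; adjusted p = 0.0170) and 303 for Ces1f (2 counts, 83.6 to 2500; adjusted p = 0.0183). Tumour 1b held 0 counts of Lep, Angptl8, Negr1 and Ces1f, so no fold is given for 1b alone. Without 1b the log2 fold changes of these genes were -9.24, -8.20, -7.62 and -7.32. Without control gland 2 they were -6.90 for Angptl8 and 10.53 for Mmp13, and without gland 3 12.37 for Mmp13. Of 14 named genes that passed, 7 did so without tumour 1a and in edgeR 0 without control gland 3 or tumour 1b, where no gene did.

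Of the fixed genes, Slc2a1 rose 9.56-fold (adjusted p = 0.0183) and Mki67 16.0-fold (adjusted p = 0.0220), while Esr1, the estrogen receptor, fell 6.40-fold from 57.3 ± 10.8 CPM to 9.35 ± 1.10 CPM (adjusted p = 0.0183) and Adipoq fell 96.8-fold (adjusted p = 0.0428), from 351.4 ± 33.8 CPM to 7.24 CPM in tumour 1a and 0.136 CPM in 1b (log2 -11.30 without 1a, and -5.61 with adjusted p = 0.0565 without 1b). Mki67 was at 4.77 on the log2 scale without control gland 2. Ecd had a log2 difference of 0.12 (SE 0.31, adjusted p = 0.824) and Mettl3 of -0.11 (SE 0.32, adjusted p = 0.849). Myc was at 1.70 (SE 0.46, adjusted p = 0.0683), Hk2 at -1.75 (adjusted p = 0.0743), Ldha at -0.72 (adjusted p = 0.364) and Pkm at 0.32 (adjusted p = 0.728). Hspa5 (1.10, adjusted p = 0.0712), Erbb2 (0.86, adjusted p = 0.150), Pgr (-4.79, adjusted p = 0.0569), Krt8 (1.46, adjusted p = 0.0646), Krt18 (0.64, adjusted p = 0.473), Trp63 (1.39, adjusted p = 0.0685), Cdh1 (1.25, adjusted p = 0.216) and Vim (1.33, adjusted p = 0.0778) did not pass either.

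Of 16 measured squamous genes, 10 rose, 0 fell and 6 did not pass (12 rose adjusted over the list alone), with a median of 5.51 (adjusted p = 6.6e-15 and adjusted p = 0.211 with an estimated correlation). That median stayed at 5.51 with Krt6b, Dsg1a and Dsg3, whose glands had no count, at their bounds. Of 16 basal and myoepithelial genes, 6 rose, 3 fell and 7 did not pass (7 rose and 3 fell adjusted over the list alone; adjusted p = 0.000285 and adjusted p = 0.327 with an estimated correlation). The 3 that fell were the smooth muscle genes Myh11 (log2 -2.58) and Mylk (log2 -1.50) and the oxytocin receptor gene Oxtr (log2 -5.41), named after their values were seen. Of 16 protease and inhibitor genes, 10 rose, 0 fell and 6 did not pass (12 rose adjusted over the list alone), with a median of 4.10, also with Mmp10 at its bound (adjusted p = 1.5e-12 and adjusted p = 0.211 with an estimated correlation). Of 21 collagen and matrix genes, 10 rose and 11 did not pass (15 rose and 1 fell adjusted over the list alone; adjusted p = 5.9e-07 and adjusted p = 0.430 with an estimated correlation). Of 19 mesenchymal genes, 8 rose and 11 did not pass (11 rose and 1 fell adjusted over the list alone; adjusted p = 7.9e-06 and adjusted p = 0.270 with an estimated correlation). Of 16 Wnt target genes, Ccnd1 (log2 3.21), Nkd2 (5.43), Lgr6 (2.57) and Dkk2 (3.82) rose and 12 did not pass (7 rose adjusted over the list alone; adjusted p = 2.5e-05 and adjusted p = 0.270 with an estimated correlation), named after their values were seen. Over these lists 51 genes passed, but 29 without control gland 1, 12 without tumour 1a, and in edgeR 0 without control gland 3 or tumour 1b (70 and 68 at unadjusted p under 0.05).

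Macrophage and neutrophil genes and some interferon genes rose in the same tumours. Of 19 macrophage genes, 10 rose, 0 fell and 9 did not pass (14 rose and 1 fell adjusted over the list alone; adjusted p = 1.6e-08 and adjusted p = 0.320 with an estimated correlation). Of 12 neutrophil genes, 7 rose and 5 did not pass (10 rose adjusted over the list alone), with a median of 5.67, also with Cxcl3 at its bound (adjusted p = 1.1e-09 and adjusted p = 0.230 with an estimated correlation). Of 18 interferon genes, Oasl2 (log2 2.53), Irf7 (2.09), Bst2 (2.84) and Isg15 (3.13) rose and 14 did not pass (8 rose adjusted over the list alone; adjusted p = 9.5e-05 and adjusted p = 0.211 with an estimated correlation), named after their values were seen. Over these lists 21 genes passed, but 11 without control gland 1, 4 without tumour 1a, and in edgeR 0 without control gland 3 or tumour 1b (32 and 29 at unadjusted p under 0.05). None of 15 B cell genes (adjusted p = 0.695, median -0.18 and mean -0.19 with camera's direction up) or 14 T and NK cell genes (adjusted p = 0.963) passed in edgeR, also adjusted over the list alone, nor any in DESeq2, in limma-voom or at unadjusted p under 0.05 (0 genes). The B cell list passed without tumour 1b (adjusted p = 0.0232, higher) and the T and NK cell list without tumour 1a (0.0297, lower), and 1 B cell gene rose without control gland 2.

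The cell cycle and metabolic lists gave these counts. Of 24 mitosis genes, 23 rose and 1 did not pass (24 rose adjusted over the list alone; median 4.05, adjusted p = 2.0e-26 and adjusted p = 0.211 with an estimated correlation). Of 23 replication genes, 10 rose and 13 did not pass (21 rose adjusted over the list alone; adjusted p = 2.9e-12 and adjusted p = 0.244 with an estimated correlation). Of 27 nucleolar genes, Nop56 rose (log2 1.37, named after its value was seen) and 26 did not pass (none adjusted over the list alone; adjusted p = 0.00645 and adjusted p = 0.430 with an estimated correlation). Of 22 adipocyte genes, 14 fell and 8 did not pass (21 fell adjusted over the list alone; adjusted p = 7.8e-20 and adjusted p = 0.211 with an estimated correlation). Of 17 lipogenesis genes, 12 fell and 5 did not pass (13 fell adjusted over the list alone; adjusted p = 2.9e-12 and adjusted p = 0.270 with an estimated correlation). Of 18 fatty acid oxidation genes, 13 fell, 4 did not pass and Cpt1a, which lets fatty acids into mitochondria, rose (log2 1.42, named after its value was seen; 17 fell and 1 rose adjusted over the list alone; adjusted p = 1.5e-11 and adjusted p = 0.211 with an estimated correlation). Of 22 oxidative phosphorylation genes, 14 fell and 8 did not pass (21 fell adjusted over the list alone; adjusted p = 7.7e-11 and adjusted p = 0.270 with an estimated correlation). The mitochondrial share, most of it mt-Rnr2, was also lower in both tumours. Over these lists 88 genes passed, but 40 without control gland 1, 6 without tumour 1a, and in edgeR 0 without control gland 3 or tumour 1b (121 and 114 at unadjusted p under 0.05). None of 18 muscle genes passed in edgeR, also adjusted over the list alone (12 at unadjusted p under 0.05, while 16 passed in DESeq2 and 0 in limma-voom), with a median of -6.58 (adjusted p = 0.000785 and adjusted p = 0.569 with an estimated correlation). Without control gland 2 all 18 fell, and against that gland alone their median was 2.18.

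Other lists passed with few members past the test, and the members given here were named after their values were seen. The unfolded protein response list was higher (adjusted p = 0.00544 and adjusted p = 0.469 with an estimated correlation), with Sdf2l1, Pdia6 and Dnajb11 rising and 20 not passing (10 rose adjusted over the list alone). The p53 target list was higher (adjusted p = 0.0384 and adjusted p = 0.443 with an estimated correlation), with Perp, a desmosome protein gene, rising and 16 not passing (4 rose adjusted over the list alone). The hypoxia list was higher (adjusted p = 0.0121 and adjusted p = 0.471 with an estimated correlation), with Ero1l and Car9 rising, Bnip3 falling and 13 not passing (8 rose and 2 fell adjusted over the list alone). The milk list was lower (adjusted p = 0.0153 and adjusted p = 0.569 with an estimated correlation), with Btn1a1 falling and 14 not passing (1 fell adjusted over the list alone), though its means of 4.98 and 4.46 log2 CPM lay above control gland 3 (4.08). Nerve genes were lower (adjusted p = 0.0158 and adjusted p = 0.443 with an estimated correlation), with 2 falling, Cdh19 among them, and 7 not passing (3 fell adjusted over the list alone), as were erythrocyte genes (adjusted p = 0.0133 and adjusted p = 0.469 with an estimated correlation), with Alas2 falling and 4 not passing (1 fell adjusted over the list alone). Over these lists 11 genes passed, but 3 and 7 without control gland 1 or 2, and in edgeR 0 without control gland 3, tumour 1a or tumour 1b (42, 35 and 27 at unadjusted p under 0.05). The list calls were lost without control gland 2 for p53 targets, milk and hypoxia (adjusted p = 0.164, 0.0595 and 0.0929), without gland 1 for milk (0.0653), without tumour 1a for nerve (0.261) and without 1b for p53 targets (0.145).

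The remaining lists did not pass. In the ECD partner list Eftud2 rose, Txnip fell and 10 genes, Ecd included, did not pass (1 rose and 1 fell adjusted over the list alone; adjusted p = 0.518). Among m6A genes Igf2bp2 rose and 14 did not pass (1 rose adjusted over the list alone; adjusted p = 0.643), with a median of -0.10 and a mean of 0.17 and camera's direction up. Among glycolysis genes Slc2a1 rose, Pfkfb3 fell and 19 did not pass (3 rose and 2 fell adjusted over the list alone; adjusted p = 0.912; median 0.04, mean -0.04, camera's direction up). Among luminal genes Krt7 rose, Esr1, Prlr and Foxa1 fell and 21 did not pass (2 rose and 4 fell adjusted over the list alone; adjusted p = 0.582; median 0.37, mean -0.30, camera's direction down). Among receptor tyrosine kinase and ligand genes Hbegf, Tgfa and Pdgfa rose, Erbb4 and Kitl fell and 11 did not pass (6 rose and 3 fell adjusted over the list alone; adjusted p = 0.235). Among endothelial genes Sox17 fell and 15 did not pass (none adjusted over the list alone; adjusted p = 0.109). Over these lists 15 genes passed, but 6 without control gland 1, 1 without tumour 1a, and in edgeR 0 without control gland 3 or tumour 1b (34 and 25 at unadjusted p under 0.05). The endothelial list passed without control gland 1 or tumour 1a (0.0273 and 0.0110) as lower, and so did the luminal list without tumour 1b (0.0344, with its median turned to -0.45). Members other than Slc2a1 and Esr1 were named after their values were seen.

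Tumour types are given as values only. Differences between them were not tested, and with 1 spindle cell and 1 papillary library a test would take their spread from the other groups. The log2 gaps use a prior count of 2, which limits them where other libraries are near 0 counts. The adenosquamous pair stood furthest above the other 5 libraries in Hmga2, a chromatin protein of fetal tissue (540 and 253 counts against at most 9), Krt6a (4096 and 1726 against at most 49), Dynap, Inhba, Ptgs2 and Mmp13, with gaps of 4.71 to 6.31. Krt6a has a near-identical copy.

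The spindle cell tumour held 203627 counts of Dcpp2 (chromosome 17, 23880880 to 23900788), 56190 of Dcpp1 and 6379 of Dcpp3, secreted proteins of mucous glands. The other 6 libraries held at most 3 counts of each. Dcpp1 and Dcpp2 overlap on the annotation and resemble each other, so the split among them is uncertain. The same tumour held 24295 counts of Dmbt1, a mucosal secreted protein, against at most 14 elsewhere, 517 of Cyp2a5 against 0, and 2009 of Mycn, a relative of Myc, against at most 33. Its mesenchymal list mean was 3.59 log2 CPM, against 4.24 to 4.81 in glands, and its Vim value was 5.75 against 7.01 to 7.93. Its luminal list mean was 4.53, against 3.92 to 4.40 in glands, and its Cdh1 value of 7.94 was the highest of the 7 libraries. Whether this profile matches the spindle cell label was not tested.

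The papillary tumour stood apart in Wfdc5 (5813 counts against at most 1), Igsf1 (1857 against at most 3), Pip, a prolactin-induced secreted protein (743 against 0), Rdh16, Apod and the casein gene Csn1s2b, with gaps of 6.52 to 9.61. Its milk protein list mean was 10.16 log2 CPM, against 4.08 to 7.49 in glands and 1.48 to 4.98 in the other tumours. Its basal and myoepithelial list mean was 2.56, against 3.24 to 4.79 in glands and 5.25 to 6.01 in the other tumours. It held 10 counts of Trp63, the basal cell regulator p63, a log2 CPM of -1.08 against 3.95 or more in every other library.

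**Figure D3:**
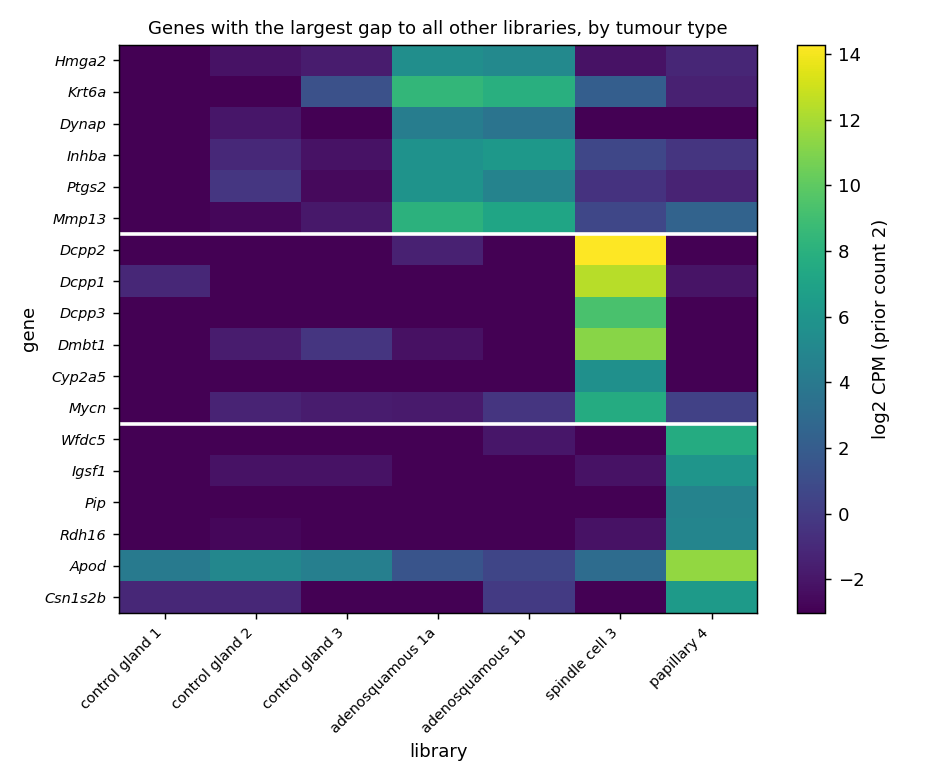
Log2 CPM (colour, prior count 2) of the 6 genes with the largest gap for the adenosquamous pair (top), the spindle cell tumour (middle) and the papillary tumour (bottom), by library. The brightest cell is Dcpp2 in the spindle cell tumour, at 14.29.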

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

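No test here was chosen after the result was seen, and the differences between tumour types were not tested. Spindle cell and papillary carcinoma had 1 library each. Among the 4 tumours, 10 of 105 lists and named genes had 1 library far from the other 3 by Dixon's ratio (its gap over the whole range), where chance gives about 1 in 20. Adenosquamous tumour 1a stood apart upward in the unfolded protein response list (ratio 0.842, mean log2 CPM 6.04 against 5.47 to 5.56), downward in the luminal list (0.907, 3.46 against 4.53 to 4.64) and upward in Ighm (0.98). Adenosquamous tumour 1b stood apart upward in the p53 target list (0.882) and Pkm (0.901) and downward in the fatty acid oxidation list (0.835). The spindle cell tumour stood apart downward in the interferon list (0.833, 2.61 against 3.56 to 3.75), in Myc (0.887) and in Tnc (0.839, 4.50 against 9.49 to 10.45). The papillary tumour stood apart downward in Trp63 (0.978).

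Several lists and genes lay on opposite sides of all 3 glands in different tumour types, and these differences were not tested. In the mesenchymal list the adenosquamous tumours lay above the glands, and the spindle cell and papillary tumours below. The adenosquamous mean was higher by 2.94 than the spindle cell and by 3.01 than the papillary value, in log2 CPM. The collagen and matrix list behaved alike (3.07 and 3.24), as did Vim (3.16 and 2.77) and, with smaller differences, the receptor tyrosine kinase list (0.82 and 1.16). The Wnt target list differed by 3.79 between adenosquamous and papillary tumours. The basal and myoepithelial list was higher in adenosquamous (by 3.12) and spindle cell tumours (by 2.69) than in the papillary tumour, as were Krt5 (8.94 and 7.58) and Trp63 (7.2 and 7.09). Myc was higher by 4.70 in the adenosquamous than in the spindle cell tumours, and the spindle cell tumour differed from the papillary by -5.16. The spindle cell tumour also differed from the papillary by -8.68 in the milk list and by -12.67 in Wap.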

How the results depend on the processing

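Most alternatives were chosen before the data were examined, and those on protein-coding genes, control gland 2 alone and pairs of libraries left out were chosen after. No paired analysis was possible because the labels give no pairing of glands with tumours. Genes passing in the tumour comparison (1199) became 3403 with DESeq2, 105 at adjusted p under 0.01, 533 with tumours 1a and 1b added together, 2503 with tumour types weighted equally and 97 to 1351 with 1 library left out. In edgeR 0 passed with control gland 2 alone (1655 at unadjusted p under 0.05) or without control gland 1 and the spindle cell tumour (3441). In the adenosquamous comparison (1525) they became 3562 with DESeq2, 2508 with no filter and 0 to 1498 with 1 library left out. In edgeR 0 passed at adjusted p under 0.01 (4399 at unadjusted p under 0.05), with control gland 2 alone (2898) or without control gland 1 and tumour 1b (3839). The other settings stayed within 1.5 times, and genes called both there and in the main analysis kept their sign. A lone tumour or gland left in its group was assumed to vary like the other libraries. Lists passing (16 and 23 of 31) became 0 and 0 with camera's estimated correlation (4 and 6 at unadjusted p under 0.05) and 7 and 12 with fry, and stayed within 1.5 times otherwise. The 7 in fry were mitosis, replication, nucleolar, oxidative phosphorylation, adipocyte, lipogenesis and fatty acid oxidation. The 12 were these and the squamous, protease, mesenchymal, interferon and neutrophil lists. Settings that left out or added libraries rest on fewer samples, and for the rest the cause was not tested. For named genes, alternatives in the tumour comparison kept the side of the threshold and direction in 1156 cases, lost the call in 343, gained it in 33 and reversed in 12, and in the adenosquamous comparison in 368, 83, 18 and 6. For list medians these were 365, 32, 27 and 10, and 280, 43, 5 and 13. With 1 library left out, tumour list medians that reversed ranged over -0.14 to 0.097 for glycolysis (0.042 with 1a and 1b added), -0.018 to 0.13 for m6A (-0.013 protein-coding), -2.68 to 2.25 for milk, -2.70 to 3.33 for B cell and -3.34 to 1.51 for T and NK cell. The single values above 0 were 0.070 without gland 2, 0.097 without tumour 3 and 0.093 without tumour 4 for glycolysis. Adenosquamous list medians ranged over -0.14 to 0.20 for glycolysis (-0.064 and -0.099 without gland 1 or 3), -5.73 to 3.23 for B cell (0.84 without 1b), -3.72 to 2.26 for T and NK cell (0.34 without 1b) and -0.45 to 0.73 for luminal. Without gland 1 and 1b they were -0.25, 0.35, -0.31 and 0.044 for glycolysis, B cell, luminal and m6A. With gland 2 alone, muscle medians were 1.22 and 2.18 and Casq1 was at 0.14. Tumour log2 fold changes ranged over -0.00557 to 0.15 for Mettl3 (-0.00944 at 10 CPM, -0.013 protein-coding) and -0.11 to 0.65 for Pkm (-0.018 without 1b, -0.038 without gland 1 and tumour 3). With limma-voom Trp63 and Vim were at -0.86 and -0.0693, and with types weighted equally Trp63, Vim and Wap at -1.11, -0.600 and -0.215. Adenosquamous values ranged over -0.018 to 0.31 for Ecd, -0.17 to 0.017 for Mettl3, -0.030 to 0.77 for Pkm and -0.39 to 1.27 for Krt18, with Pkm and Krt18 at -0.29 and -0.39 without gland 1 and 1b. With a prior count of 0.5, 122 list means per tumour moved by less than the SD of the glands and 2 by more, both to -0.62 (adipocyte in tumour 3, squamous in tumour 4). Depth limits low genes most in control gland 1, with 5148438 counts of which 64.83% were mitochondrial.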

Other observations

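All tests in this part were chosen after the values they measure had been seen. The spindle cell tumour had the highest Mycn and lowest Myc of the 7 libraries: 2009 counts of Mycn and 13 of Myc, where the other tumours had 2 to 33 of Mycn and 292 to 1439 of Myc. Ddx1 and Nbas, the neighbours of Mycn on chromosome 12, were at 6.32 and 5.21 log2 CPM there, against 5.54 to 6.33 and 3.90 to 5.50 in the other libraries. The same tumour held 1794 counts of Pax9, 603 of Muc5b and 206 of Sox2, against at most 31, 2 and 3 in the other libraries.

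Adenosquamous tumour 1b held 4956 counts over 9 genes of the inner root sheath of the hair follicle, 8 of which had 10 or more counts, against 4 to 27 summed counts in the other 6 libraries. Tchh, which encodes trichohyalin, gave 4097 of them, with Krt73 at 204, Krt28 at 189 and Krt72 at 101. It also held 20275 counts of the macrophage elastase gene Mmp12, against 353 in tumour 1a. Gene models that resemble satellite repeats took 9.19% of its counts and 0.964% in control gland 1, the libraries with the lowest totals of their groups, against at most 0.35% in the other 5.

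Of the 35 ways to split the 7 libraries into 3 and 4, 1, the real split, gave 1199 genes, and the highest other split gave 1, so chance is argued against for this count, although 1 of 35 is the smallest share this design can give.

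Control glands 1 and 3 held skeletal muscle transcripts, with Ttn at 2.13% and 3.31% of counts and at 0.007% in control gland 2. In both, 17 of 17 muscle list genes were at least 4-fold higher than in control gland 2, which restates the list means that prompted the question. Whether fibres taken with the gland or something else brought these transcripts stays open. Whether muscle made the fall of oxidative genes in tumours is open. Against control gland 2, the list medians stayed at -0.99 for oxidative phosphorylation and -2.08 for fatty acid oxidation, but this rests on 1 library without muscle transcripts. Ucp1, a gene of the adipocyte list named after its values were seen, was at 305.4 CPM in that gland. Glands 1 and 3 had 229.9 and 37.3 CPM, tumour 1a had 43.3 and the other tumours at most 0.408. Whether the fat content of that gland made the remaining fall was not tested. Differences in the site or age of the glands were not tested.

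The Dcpp and Dmbt1 transcripts of the spindle cell tumour were weighed against tissue taken with the tumour. Salivary tissue stays open for Dcpp, since no table here holds a salivary profile and Muc5b goes with it: 11 other salivary transcripts, 1 of which (Amy1) the control glands also express, gave 676 counts, 0.254% of the 266196 Dcpp counts, with Muc5b at 603, Muc19 at 26, Smgc at 1 and Amy1 at 0. Airway or nasal tissue stays open for Dmbt1 too: 13 transcripts of these tissues, none at 10 CPM in the glands, gave 1189 counts, 4.89% of the Dmbt1 count, with Muc5b at 603, Cyp2a5 at 517, Bpifb1 at 21 and Scgb1a1 at 0. A mucous secretory programme in the tumour cells stays open as well and was not tested, nor was a link to the spindle cell type, which had 1 library.

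Neighbouring genes of chromosome 9 were raised together in adenosquamous tumour 1a. Among 20 neighbouring genes between 3403592 and 8134294 (GRCm38), 9 lay at least 1 log2 unit above all other libraries, among them Yap1 (9.13 log2 CPM against 4.90 to 5.70), Birc2, Birc3, Tmem123, Msantd4 and Aasdhppt. Chance clustering is argued against (permutation p = 0.0001, the smallest that 10000 shuffles give; adjusted p = 0.0007 over the 7 libraries scanned), as are reads shared within families, since 6 of the 9 genes belong neither to the Birc nor to the Mmp family. The adenosquamous type stays open, with 1 other such library: at the 10 genes of the run where 1a lay at least 1 log2 unit above the 5 libraries of other types, tumour 1b had a median difference of -0.16 from their median, and 1a 3.28, while Mmp13 was raised in both (8.08 and 7.18 log2 CPM). A gain of DNA copies in that tumour is a candidate explanation that counts cannot separate from regional activation, and genes between, such as Dync2h1 and Dcun1d5 (4.69 and 4.90 log2 CPM), were within the range of the other libraries. In the same scan the papillary tumour had 9 such genes on chromosome 2, from 26888628 to 28583751 (adjusted p = 0.0010), control gland 2 had 4 Gimap genes on chromosome 6 (adjusted p = 0.0362), and the other 4 libraries had adjusted p from 0.104 to 0.989.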
